A study of Homo sapiens with 24 samples.

How the data were processed

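RNA of 2 inflammatory breast cancer lines, SUM149PT and SUM190PT, was measured on 24 Affymetrix Human Gene 1.0 ST arrays, 12 per line and 3 per group. Per the labels' protocols RNA was purified on columns, checked on a Bioanalyzer and amplified with a kit for small amounts before hybridization, and the 3 arrays of a group came from independent experiments. Per the submitters' processing notes the authors made the values with RMA in Affymetrix Expression Console, versions not stated: background correction, quantile normalization and summary per probe set. The deposited values are log2 expression, which the range of the values fitted, and whether both lines were normalized together is not stated. Treatment lasted 48 h in every group. All 24 columns were used, the number of unused columns was 0 and no value was missing. Array values carry no count, so the number of arrays limits the precision, as their error bars and SE show.

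The table held 33297 probe sets. The annotation listed 21214 of these, 19460 with a single gene symbol and 1754 with several, and 12083 had no entry. Of the single-gene probe sets 19429 matched a human RefSeq gene by gene identifier, and 0 symbols had to be updated. The probe set with the highest mean over all 24 arrays stood for each of the 769 genes with more than 1, which gave 18417 genes, and no filter on intensity was applied. Probe sets with several genes or without an entry were left out of the main tests because their signal could not be given to 1 gene. TUBB3 lay only on probe sets shared by several genes and was left out for that reason. Some further genes of the lists were not analysed here.

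Groups were compared with limma 3.58.1 in R 4.3.3 (linear models with empirical Bayes variances, two-sided, with statmod 1.5.0), in a fit over the 12 arrays of a line for the 12 contrasts within lines and over all 24 arrays for the 3 contrasts between lines. Each of the 15 contrasts was adjusted over 18417 genes by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05; a further count asked for a 2-fold change. A between-line contrast is the SUM149PT value or change minus that of SUM190PT. For each gene the log2 fold change and its standard error come from the fit, and group means carry the SD of 3 arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

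Before the data were examined, 34 gene lists with 652 members (588 measured) were fixed: cell-cycle inhibitors and growth arrest, spindle and kinetochore, cytokinesis, G2/M, DNA replication, homologous recombination, linker and polyadenylated histones, tubulin and microtubule regulators, histone deacetylases, histone acetyltransferases, pro-apoptotic, anti-apoptotic, cholesterol synthesis, fatty acid synthesis, estrogen response, interferon response, antigen presentation, unfolded protein response, heat shock, NF-kB and inflammatory cytokines, epithelial junctions and keratins, mesenchymal, inflammatory breast cancer and angiogenesis, metallothionein, ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, neuronal, germline, basal and luminal breast markers, and markers of fibroblasts, leukocytes and endothelium, as other cells a culture could hold. Each list was tested with camera (preset correlation between genes 0.01), which compares a list with all other genes, again with the correlation estimated from the arrays, and with fry, which asks whether the genes of a list move one way. List p were adjusted over the 34 lists of a contrast, and a list is called on camera's adjusted p unless fry is named. The rule for named genes, also set before the data were examined, took the 8 largest rises and 8 largest falls with CG-1521 against vehicle in each line, and 4 and 4 in other contrasts, among genes that passed and whose 3 treated arrays all lay on one side of the 3 control arrays (not asked of interactions). Symbols of uncharacterized loci, small RNAs, olfactory receptors and open reading frames were skipped. Up to 4 members per list were named by size among those past the threshold, or the smallest p where none passed, and CDKN1A, ESR1, ESR2, GPER1, PGR, ERBB2, EGFR, TFF1, GREB1 and BIRC5 were always looked up.

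Whether replicate numbers pair the arrays of 2 groups was checked by correlating, across genes, each array's deviation from its group mean between arrays of the same number. All 3 pairs exceeded 0.1 only for SUM190PT estradiol against vehicle (0.443, 0.229 and 0.729) and SUM190PT combination against CG-1521 (0.518, 0.434 and 0.502), so the replicate number entered as a block in an alternative. In SUM149PT the pairs reached 0.23, 0.15 and 0.054 for estradiol against vehicle and 0.144, 0.097 and 0.11 for the combination against CG-1521. Alternatives were the replicate block, only the groups compared, all 24 arrays in one fit, quantile normalization, centring of each array on its median, removal of the dimmest genes, the mean of a gene's probe sets, all probe sets, trend and robust variances, array weights and leaving out each array in turn. The overlap of calls between lines was tested with Fisher's exact test. To see whether a count exceeds chance, arrays were regrouped into all 10 splits of 6 arrays, or 100 drawn splits for interactions, with fixed seeds.

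The procedure was tested on simulated data with changes planted on the spread of each line. In SUM149PT it recovered 59.7% of planted changes of 0.5 log2, 95.5% of 1 and 100% of 2, with 6.08% of calls false. In SUM190PT it recovered 35.8%, 80.6% and 100% with 8.86% false, and between lines 16.4%, 79.1% and 100% with 1.52% false. The simulated noise was independent between genes and equal across arrays. These rates therefore do not cover deviations that many genes of an array share, as on some SUM190PT arrays.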

Results

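Gene expression was measured on 24 arrays from 2 human inflammatory breast cancer lines, SUM149PT and SUM190PT, which the labels give as estrogen receptor negative. Inflammatory breast cancer is an aggressive form of the disease in which tumour cells block the lymph vessels of the skin. Each line was treated for 48 h with vehicle, with 10 nM 17β-estradiol, with CG-1521, or with estradiol and CG-1521 together, which made 8 groups of 3 arrays. The series title names CG-1521 as a histone deacetylase inhibitor. Deacetylases remove acetyl groups from histones and other proteins. CG-1521 was given at 7.5 µM to SUM149PT in serum-containing medium and at 5 µM to SUM190PT in serum-free medium, so line, dose and medium changed together. The arrays gave 1 value per gene for 18417 genes. Correlations across genes between arrays of a group were 0.9946 to 0.996 in SUM149PT and 0.9807 to 0.9957 in SUM190PT. The third vehicle and the third estradiol arrays of SUM190PT stood apart. The median of the DNA replication genes lay at −1.63 and −1.72 (log2) against the other arrays of their groups. Each array carries the RNA of many cells, and the 3 arrays per group limit the precision of every value.

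The 2 lines were first compared in vehicle, which asks how they differed before any drug. SUM190PT expressed genes of the luminal epithelium and SUM149PT genes of the basal epithelium and of mesenchymal cells. Of 16 measured luminal markers, 14 were lower in SUM149PT and 0 higher (median log2 difference, SUM149PT minus SUM190PT, −2.86). Among these, AGR2, a secretory-pathway isomerase, differed by −7.04 (SE 0.149). The receptor tyrosine kinase ERBB2 differed by −5.41 (SE 0.129) and its neighbour GRB7 by −4.47 (SE 0.168, n = 3 per line). Of 10 basal markers 9 were higher in SUM149PT (median 1.42), including the laminin chain LAMB3 at 4.95 (SE 0.127), the keratin KRT5 at 4.90 (SE 0.182) and EGFR at 2.84 (SE 0.125). Of 14 mesenchymal genes 12 were higher (median 1.62), with fibronectin FN1 at 5.35 (SE 0.258) and the repressor SNAI2 at 4.46 (SE 0.147). The largest single differences were in H3C11, a histone H3 gene (7.10, SE 0.121), complement C3 (6.22, SE 0.147), the actin bundler PLS3 (5.98, SE 0.097) and the caveolar coat gene CAV1 (5.72, SE 0.185) towards SUM149PT. Towards SUM190PT they were in CRISP3 (−8.49, SE 0.159), MUCL1 (−8.16, SE 0.15), the death ligand gene TNFSF10 (−7.61, SE 0.249) and the adhesion gene CEACAM6 (−7.55, SE 0.293). ESR1, the gene of estrogen receptor alpha, was low in both lines and did not differ past the threshold (0.06, adjusted p = 0.741).

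Metabolic and inflammatory genes also separated the lines in vehicle. Of 18 cholesterol synthesis genes 14 were lower and 2 higher in SUM149PT (median −0.85), and of 12 fatty acid synthesis genes 9 were lower and 2 higher (median −1.33). HMGCS1, the cytosolic synthase of the sterol pathway, was at −1.71 (SE 0.207) and fatty acid synthase FASN at −2.43 (SE 0.216). Genes of the unfolded protein response, which relieves stress in the endoplasmic reticulum, were lower in 13 of 19 (median −0.87). Of 19 genes of NF-kB and inflammatory cytokines 13 were higher and 2 lower in SUM149PT (median 0.95), with interleukin IL1A at 4.26 (SE 0.112). The deacetylase gene HDAC1 was higher by 3.74 (SE 0.188), and BRCA1, a repair gene, lower (−3.74, SE 0.376). Spindle genes were higher in 23 of 29 (median 1.31), cytokinesis genes in 14 of 25 with 2 lower and G2/M genes in 10 of 18 with 1 lower. DNA replication genes were higher in 13 of 29 (median 0.77). The third SUM190PT vehicle array lay low in these cell-cycle lists. Without it and the third estradiol array the spindle median was 0.839, that of cytokinesis genes 0.377 and that of DNA replication genes 0.329. Tubulin genes were higher in 15 of 28 with 4 lower and ribosomal protein genes in 13 of 22 with 2 lower. Junction and keratin genes were lower in 9 of 17 with 3 higher. In limma, 8592 genes differed at a Benjamini-Hochberg adjusted p under 0.05, 4517 higher and 4075 lower in SUM149PT, of which 1672 and 1346 at least 2-fold. By camera the luminal list (adjusted p = 2.57e-11) and the mesenchymal list (adjusted p = 2.69e-06) were called and held at adjusted p = 0.0133 and 0.00672 with an estimated correlation. The other 12 called lists did not hold. With an estimated correlation the adjusted p was 0.114 for basal markers, 0.335 for NF-kB, fatty acid and junction genes, 0.41 for cholesterol, 0.416 for ribosomal and 0.454 for unfolded protein response genes. It was 0.528 for tubulin, 0.604 for cytokinesis, 0.629 for spindle, and 0.651 for G2/M and DNA replication genes. Without the third vehicle and estradiol arrays of SUM190PT the calls for cytokinesis (adjusted p = 0.0664), G2/M (0.113), DNA replication (0.115) and junction genes (0.0832) ended.

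What CG-1521 changed in SUM149PT was asked by comparing it with vehicle. Genes of cell division fell together. All 29 measured genes of the mitotic spindle and kinetochore fell (median −1.83), among them the kinetochore gene NDC80 (−2.27, SE 0.089), the spindle-pole gene ASPM (−2.23, SE 0.093) and the motor gene KIF11 (−2.16, SE 0.146). Of 25 cytokinesis genes 16 fell and 2 rose (median −1.23), including the kinesin KIF20A (from 9.80 ± 0.058 to 7.003 ± 0.086, SD, n = 3) and the anillin gene ANLN (−2.23, SE 0.086). All 18 G2/M genes fell (median −1.64), with MYBL2 at −2.08 (SE 0.089) and cyclin CCNA2 at −2.03 (SE 0.079). Of 29 DNA replication genes 28 fell (median −1.33), with thymidylate synthase TYMS at −2.02 (SE 0.076). All 15 homologous recombination genes fell (median −1.19), with the nuclease gene EXO1 at −1.88 (SE 0.114). The survivin gene BIRC5 fell by 1.72 (SE 0.080). Of 12 linker and polyadenylated histone genes 8 fell (median −0.49). The linker histone genes H1-5 (−3.11, SE 0.099) and H1-1 (−2.93, SE 0.108) and the histone gene H2BC14 (−2.997, SE 0.090) were among the 8 largest falls of all genes. The cell-cycle inhibitor gene CDKN1A, which encodes p21, rose by 1.45 (SE 0.108), from 7.02 to 8.46, and the growth-arrest gene GADD45A by 0.92 (SE 0.089). Of 13 such genes 5 rose and 1 fell (median 0.21, or 0.136 without CG-1521 replicate 2). By camera the adjusted p was 3.87e-30 for spindle, 6.62e-10 for cytokinesis and 4.9e-18 for G2/M genes, and these held with an estimated correlation (adjusted p = 0.0245, 0.0245 and 0.0178). It was 3.29e-23 for DNA replication, 9.49e-13 for recombination, 0.00025 for histone and 0.00996 for CDK inhibitor genes, but adjusted p = 0.0621, 0.0621, 0.0621 and 0.0673 with an estimated correlation. Adjusted over the list alone, the counts were the same except for cytokinesis, where 3 rose and 16 fell. The spindle, G2/M, cytokinesis and tubulin lists follow themes that the study is known to have taken up, so they were not chosen blind and are not independent evidence of their direction.

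Genes of sterol synthesis and of protein folding in the endoplasmic reticulum rose in SUM149PT under CG-1521. Of 18 cholesterol synthesis genes 16 rose (median 0.78), including the sterol oxidase MSMO1 (2.23, SE 0.103), HMGCS1 (2.13, SE 0.097) and the desaturase SC5D (1.53, SE 0.089), at camera adjusted p = 1.79e-11, or adjusted p = 0.0444 with an estimated correlation. All 19 unfolded protein response genes rose (median 0.86), among them the transcription factor gene DDIT3 (2.16, SE 0.111), the chaperone cofactor DNAJB9 (1.73, SE 0.099) and HERPUD1 (1.71, SE 0.110), at adjusted p = 5.6e-15, or 0.0245 with an estimated correlation. Of 19 NF-kB and cytokine genes 9 rose and 4 fell (median 0.28), and the secreted signals IL1A (2.14, SE 0.082), CXCL8 (2.03, SE 0.124) and CXCL2 (1.97, SE 0.209) rose most. The call at adjusted p = 0.00162 became adjusted p = 0.0621 with an estimated correlation. Mesenchymal genes fell in 8 of 14 and rose in 1 (median −0.46, adjusted p = 0.00376, or adjusted p = 0.0621 with an estimated correlation). TGFBI fell by 2.36 (SE 0.103), the cadherin CDH2 by 2.29 (SE 0.136) and vimentin VIM by 1.56 (SE 0.122). Without the dimmest 50% of genes this call ended (adjusted p = 0.0868). Of 12 histone acetyltransferase genes 7 fell and 0 rose (median −0.33, adjusted p = 0.000757, or adjusted p = 0.142 with an estimated correlation), HAT1 most (−1.04, SE 0.085). Heat shock genes fell in 8 of 13 (median −0.32), oxidative phosphorylation genes in 8 of 22 with 1 risen (median −0.20), and glycolysis genes in 10 of 20 with 1 risen (median −0.30), each at adjusted p = 0.0348. With an estimated correlation they were at adjusted p = 0.263, 0.528 and 0.672. These 3 calls ended under quantile normalization (adjusted p = 0.11, 0.172 and 0.121). Single arrays decided them too. The heat shock call ended without CG-1521 replicate 1 (adjusted p = 0.052), replicate 2 (0.0686, median −0.209) or vehicle replicate 1 (0.0529). That for oxidative phosphorylation ended without CG-1521 replicate 2 (0.0686), replicate 3 (0.0538) or vehicle replicate 1 (0.0776), and that for glycolysis without CG-1521 replicate 3 (0.085), vehicle replicate 1 (0.0506) or vehicle replicate 2 (0.0746).

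The genes that rose most in SUM149PT were SPX, a peptide hormone gene (from 3.85 ± 0.076 to 7.78 ± 0.266, SD, n = 3) and AGR2 (3.88, SE 0.127). Next were the aldo-keto reductases AKR1C1 (3.77, SE 0.097), AKR1B10 (3.69, SE 0.081) and AKR1C3 (3.69, SE 0.122), enzymes that reduce aldehydes and ketones with NADPH. CLGN, a chaperone of the endoplasmic reticulum (3.66, SE 0.129), complement C1S (3.55, SE 0.082) and the cystine transporter SLC7A11 (3.37, SE 0.127) followed. Besides histone genes and KIF20A, the largest falls were in the matrix gene EFEMP1 (−3.30, SE 0.128), the retinoid-responsive gene RARRES1 (−3.29, SE 0.166), the skin caspase CASP14 (−3.22, SE 0.181) and the growth factor TGFB2 (−2.88, SE 0.137). Tubulin and microtubule genes went both ways, 10 up and 13 down of 28 (camera adjusted p = 0.941). The microtubule-associated MAP1B (1.93, SE 0.173) and MAP2 (1.81, SE 0.168) rose and the destabilizer STMN1 fell (−1.22, SE 0.077). Among 18 deacetylase genes 4 rose, HDAC9 most (1.14, SE 0.091), and 4 fell, with SIRT1 at −0.67, HDAC2 at −0.55 and HDAC1 at −0.52 (adjusted p = 0.941 for the list). Apoptosis genes were not called as groups. Of 23 pro-apoptotic genes 3 rose and 4 fell, with the apoptosome gene APAF1 at −0.73 (SE 0.081), and 3 anti-apoptotic genes rose and 1 fell of 8, with BCL2L1 at 0.69 (SE 0.084). Basal markers rose in 5 of 10 and fell in 1 (adjusted p = 0.0536, or 0.0283 under quantile normalization, lost at adjusted p = 0.0835 with an estimated correlation), led by LAMB3 (1.75, SE 0.087). Luminal markers rose in 4 and fell in 4 of 16, with AGR2 up and the transcription factor GATA3 down (−0.92, SE 0.135). ESR1 (0.07, adjusted p = 0.633), ERBB2 (−0.28, adjusted p = 0.0706) and EGFR (−0.06, adjusted p = 0.645) did not pass.

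Among the other lists in SUM149PT, fatty acid synthesis genes rose in 5 and fell in 3 of 12 (adjusted p = 0.177) and estrogen response genes rose in 3 and fell in 10 of 25 (0.0953). Interferon genes rose in 3 and fell in 3 of 23 (0.523) and antigen presentation genes fell in 5 of 10 (0.0709), with the immunoproteasome gene PSMB9 at −0.82 (SE 0.081). Junction and keratin genes rose in 3 and fell in 3 of 17, with the claudin gene CLDN1 at 1.67 (SE 0.187). Inflammatory breast cancer and angiogenesis genes rose in 3 and fell in 4 of 14, with CAV1 at −1.65 (SE 0.106). Ribosomal protein genes rose in 2 and fell in 2 of 22, neuronal genes rose in 1 and fell in 2 of 25, germline genes fell in 1 of 16 and none of 8 metallothioneins passed. Markers of other cell types were not called as lists. Fibroblast markers fell in 4 of 12 (adjusted p = 0.0608, or 0.0329 under quantile normalization, lost at adjusted p = 0.0856 with an estimated correlation), with FAP at −2.22 (SE 0.089). Leukocyte markers rose in 1, the lysosomal CD68 (0.88, SE 0.079), and fell in 1 of 13, and none of 10 endothelial markers passed. In SUM149PT, adjusted over the list alone, fatty acid genes rose in 6 and fell in 5, mesenchymal genes rose in 2 and fell in 8, acetyltransferase genes fell in 8, tubulin genes rose in 11 and fell in 13, basal markers rose in 6 and glycolysis genes in 2. In limma, 6319 genes passed in SUM149PT, 2655 up and 3664 down, of which 323 and 553 changed at least 2-fold. For 8213 genes (44.6%) the 3 treated arrays lay wholly to one side of the 3 vehicle arrays, against 10% by chance.

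CG-1521 was compared with vehicle in SUM190PT in the same way. Heat shock genes, which code for protein chaperones, rose in 13 of 13 (median 1.19). HSPA6 went from 5.47 ± 0.219 to 10.36 ± 1.51 (SD, n = 3). HSPB8 (4.54, SE 0.365), HSPH1 (2.82, SE 0.335), the cochaperone BAG3 (2.64, SE 0.315) and DNAJB1 (2.27, SE 0.230) rose too. The small heat shock protein gene CRYAB rose by 4.66 (SE 0.484) and the stress-induced ZFAND2A by 3.87 (SE 0.324). Cholesterol synthesis genes fell in 13 of 18 (median −0.95), with the isomerase EBP at −1.31 (SE 0.245), DHCR7 at −1.22 (SE 0.167) and SQLE at −1.22 (SE 0.249). Fatty acid synthesis genes fell in 9 of 12 (median −1.13), with the lipogenic THRSP at −3.04 (SE 0.186), the desaturase FADS2 at −2.69 (SE 0.377) and FASN at −1.25 (SE 0.273). Luminal markers fell in 10 of 16 (median −0.63), led by the transcription factors TFAP2B (−2.47, SE 0.156), SPDEF (−1.84, SE 0.216) and GATA3 (−1.46, SE 0.182). Basal markers rose in 4 and fell in 1 of 10 (median 0.35), with annexin ANXA1 at 2.02 (SE 0.169), KRT16 at 1.46 (SE 0.284) and EGFR at 1.07 (SE 0.158). Without the third vehicle and estradiol arrays 5 basal markers rose (median 0.548). Oxidative phosphorylation genes fell in 14 of 22 (median −0.43), with NDUFV1 of complex I at −0.93 (SE 0.148). By camera the adjusted p was 1.08e-12 for heat shock, 2.76e-09 for cholesterol, 1.41e-07 for fatty acid, 1.55e-06 for luminal, 0.00631 for basal and 5.54e-07 for oxidative phosphorylation genes. None held with an estimated correlation (adjusted p = 0.399, 0.399, 0.399, 0.399, 0.517 and 0.444). Fry, which does not compare a list with the other genes, called 11 of the 34 lists. Heat shock genes, adjusted over the list alone, rose in 13, and cholesterol genes fell in 15, fatty acid genes in 11, luminal markers in 11 and oxidative phosphorylation genes in 16, and basal markers rose in 5 and fell in 1.

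Cell division genes also fell in SUM190PT. Of 29 spindle genes 21 fell (median −1.57), with KIF4A at −2.25 (SE 0.441) and ASPM at −2.23 (SE 0.366). Of 18 G2/M genes 14 fell (median −1.45), with CDC20, an activator of the anaphase-promoting complex, at −2.04 (SE 0.293). Of 25 cytokinesis genes 11 fell and 1 rose (median −0.60), with KIF20A at −2.64 (SE 0.480). BIRC5 fell by 1.40 (SE 0.344). DNA replication genes passed in 1 of 29, the clamp loader RFC3 (−1.77, SE 0.407), at a list median of −0.90. Recombination genes fell in 2 of 15 (median −0.81), with the Fanconi gene FANCC at −0.81 (SE 0.211). The third vehicle array lay low in these genes. Without it and the third estradiol array 29 of 29 spindle genes fell (median −2.04), as did 17 of 18 G2/M genes and 27 of 29 DNA replication genes (median −1.41). In that setting 13 of 15 recombination genes and 14 cytokinesis genes fell, and 1 cytokinesis gene rose. The 2 arrays were left out after being seen low in DNA replication genes, so larger falls without them are not separate support. On the third vehicle array the median level of DNA replication genes was 7.257, below 7.486 on the third CG-1521 array. The third estradiol array lay at 7.212, below 7.442 on the third combination array. Spindle genes were lower on the third CG-1521 array than on the third vehicle array (5.923 against 6.862). CDKN1A rose by 1.40 (SE 0.166), GADD45A by 1.74 (SE 0.175) and CDKN2B, another CDK inhibitor gene, by 1.15 (SE 0.138). Of 13 such genes 4 rose and 2 fell (adjusted p = 0.0841). Without the 2 arrays this list was called at adjusted p = 0.00761, but adjusted p = 0.294 with an estimated correlation. By camera the adjusted p was 3.08e-11 for spindle, 2.76e-09 for G2/M, 0.0135 for cytokinesis, 0.000795 for DNA replication and 0.00171 for recombination genes. With an estimated correlation it was adjusted p = 0.534, 0.504, 0.646, 0.646 and 0.646. Vehicle replicate 1 decided 3 of these calls. Without it cytokinesis was at adjusted p = 0.132, DNA replication at 0.105 (median −0.593) and recombination at 0.0863. Adjusted over the list alone, 27 spindle, 18 G2/M, 15 cytokinesis, 1 DNA replication and 6 recombination genes fell and 3 cytokinesis genes rose. As in SUM149PT, the spindle, G2/M, cytokinesis and tubulin lists are not independent evidence.

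Inflammatory and interferon genes rose in part in SUM190PT. Of 19 NF-kB and cytokine genes 6 rose and 0 fell (median 0.34), with LIF at 2.41 (SE 0.272) and CXCL8 at 2.14 (SE 0.270). Of 23 interferon response genes 6 rose (median 0.27), with the antiviral IFIT2 at 3.30 (SE 0.530) and RSAD2 at 2.65 (SE 0.480). The calls at adjusted p = 0.00188 and 0.00562 were lost at adjusted p = 0.532 and 0.646 with an estimated correlation, and without the dimmest 50% of genes interferon was at 0.372. The interferon median was 0.466 without CG-1521 replicate 1 and 0.101 without CG-1521 replicate 3. Unfolded protein response genes rose in 4 and fell in 2 of 19 (median 0.26, adjusted p = 0.0436, or adjusted p = 0.646 with an estimated correlation), with ATF3 at 2.70 (SE 0.520) and the chaperone HSPA5 at 0.86 (SE 0.159). This call ended under quantile normalization (adjusted p = 0.169) and centring (0.116) and without CG-1521 replicate 1 (0.188), vehicle replicate 1 (0.105) or vehicle replicate 2 (0.19), and the median was 0.012 without CG-1521 replicate 1 and 0.14 without vehicle replicate 1. The third vehicle array lay high in this list. Without it and the third estradiol array 7 genes rose and 2 fell (median 0.49, adjusted p = 0.000671, or adjusted p = 0.416 with an estimated correlation). Tubulin and microtubule genes rose in 7 and fell in 2 of 28 (median 0.11, adjusted p = 0.0186, or adjusted p = 0.646 with an estimated correlation), with MAP1B at 2.80 (SE 0.275), MAP2 at 2.44 (SE 0.331) and STMN1 at −1.36 (SE 0.386). Without vehicle replicate 3 the call ended (median 0.05, adjusted p = 0.168), and without vehicle replicate 1 and CG-1521 replicate 2 in turn the median was 0.195 and 0.074. HDAC9 rose by 1.196 (SE 0.195), 1 of 2 risen among 18 deacetylase genes. In counts adjusted over the list alone, 8 NF-kB and 8 interferon genes rose, 6 unfolded protein response genes rose and 3 fell, and 8 tubulin genes rose and 3 fell.

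Single genes with the largest rises in SUM190PT were BPIFC, of a family of lipid-binding proteins (4.99, SE 0.379), HSPA6, CRYAB and HSPB8. They were followed by the interleukin-1 receptor antagonist IL1RN (3.92, SE 0.414), ZFAND2A, AKR1B10 (3.68, SE 0.398) and CLIC2 (3.54, SE 0.388). The largest falls were in the cytochrome P450 gene CYP4Z1 (from 8.83 ± 0.949 to 4.46 ± 0.318, SD, n = 3) and its pseudogene CYP4Z2P (−3.07, SE 0.219). Large falls were also in the fibrinogen chains FGB (−3.47, SE 0.489) and FGG (−3.47, SE 0.419), LRRC31 (−3.44, SE 0.323), the mucin MUC19 (−3.41, SE 0.329), SCGB1D2, a secretoglobin (−3.18, SE 0.536), and CLCA2 (−3.13, SE 0.219). ERBB2 fell by 0.52 (SE 0.135), from 12.59 to 12.07, and the estrogen-binding receptor gene GPER1 by 0.33 (SE 0.104), while ESR1 was at −0.14 (adjusted p = 0.533). The GPER1 fall was not seen beside estradiol. With the combination GPER1 was at −0.08 against vehicle (SE 0.104, limma adjusted p = 0.701) and at 0.49 against estradiol (SE 0.104, limma adjusted p = 0.0056). The remaining lists were not called. Estrogen response genes rose in 2 and fell in 7 of 25 (adjusted p = 0.0515, or 0.024 with the replicate block, lost at adjusted p = 0.395 with an estimated correlation), histone genes rose in 1 of 12 and acetyltransferase genes changed in 0 of 12. Pro-apoptotic genes rose in 2 and fell in 2 of 23, anti-apoptotic genes fell in 1 of 8, antigen presentation genes rose in 1 and fell in 1 of 10, and junction and keratin genes rose in 4 and fell in 3 of 17. None of 14 mesenchymal genes, 8 metallothioneins, 16 germline genes, 12 fibroblast markers or 10 endothelial markers passed. Inflammatory breast cancer genes rose in 2 of 14 (adjusted p = 0.108), or in 4 without the third vehicle and estradiol arrays, where the list was called (adjusted p = 0.0485, or adjusted p = 0.292 with an estimated correlation). Glycolysis and hypoxia genes rose in 6 of 20 with NDRG1 at 2.50 (SE 0.530), neuronal genes in 1 of 25, and leukocyte markers in 1 of 13, again CD68 (1.91, SE 0.154). Ribosomal protein genes rose in 1 and fell in 1 of 22. In limma, 3053 genes passed in SUM190PT, 1532 of them up and the rest down (50.2% up, or 66.4% up with each array centred). Of these, 363 rose and 346 fell at least 2-fold. For 5804 genes (31.5%) the groups did not overlap, against 10% by chance. Leaving out CG-1521 replicate 1 gave 1567 genes and leaving out vehicle replicate 2 gave 1878.

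**Figure D1:**
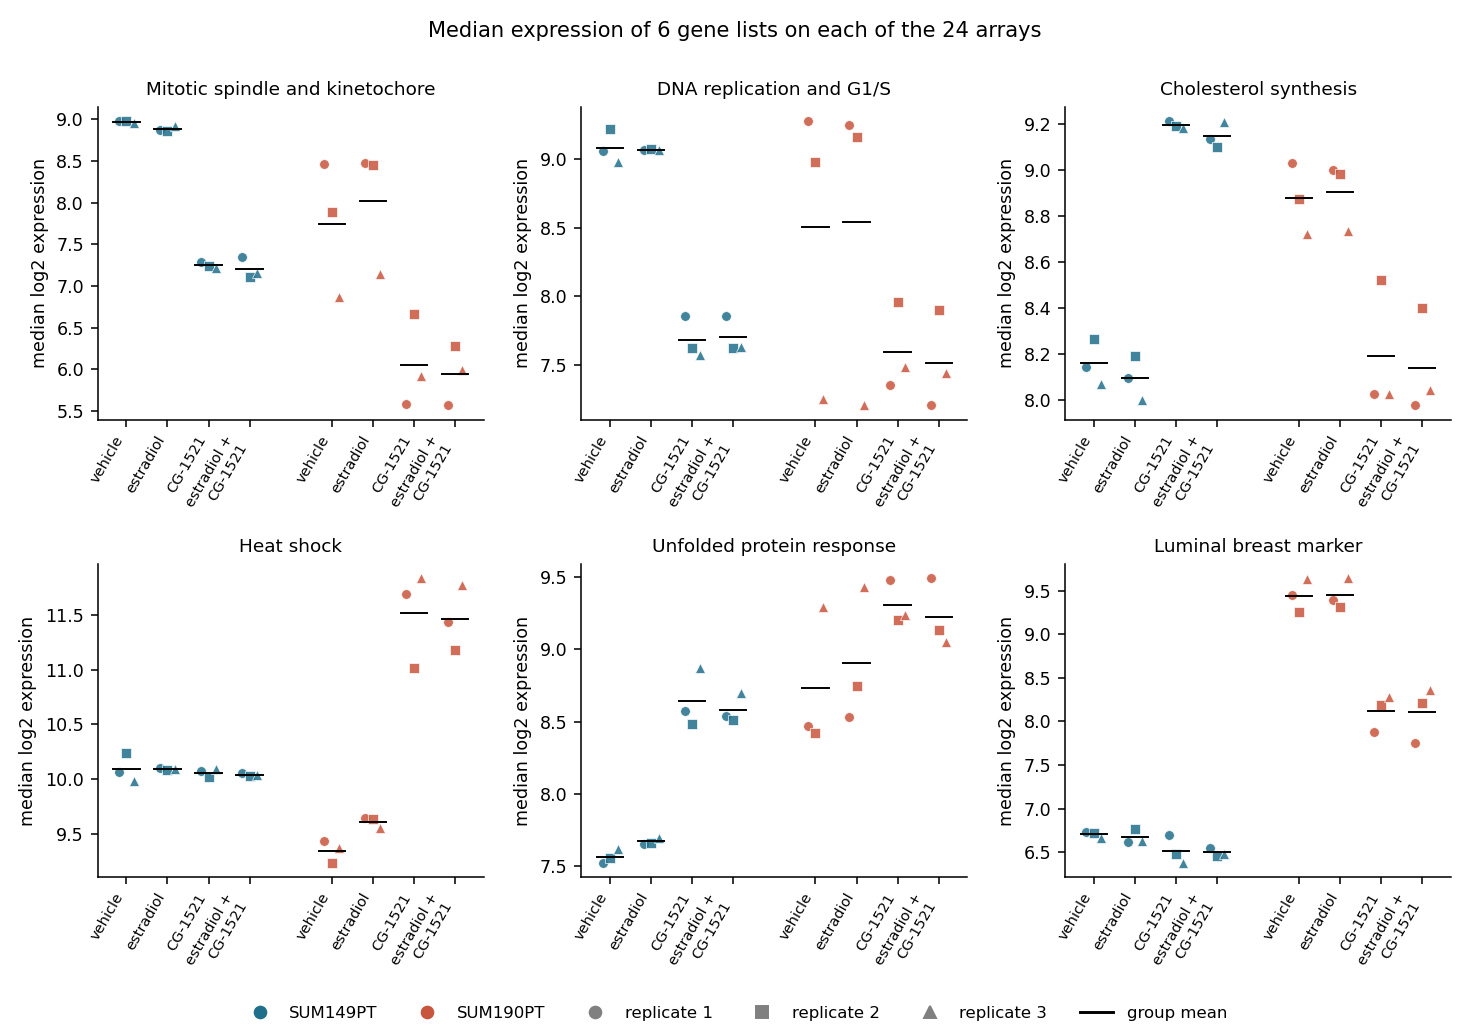
Each panel shows the median log2 expression of the measured genes of 1 list on each of the 24 arrays, by treatment, with colour for the line, marker shape for the replicate and a bar for the group mean of 3 arrays. By the median of the genes' log2 changes, which differs from the change of the plotted medians, the spindle list fell with CG-1521 in both lines (−1.83 and −1.57). By that measure cholesterol synthesis moved apart (0.78 in SUM149PT, −0.95 in SUM190PT). The third SUM190PT vehicle and estradiol arrays lay low in DNA replication genes.

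**Figure D2:**
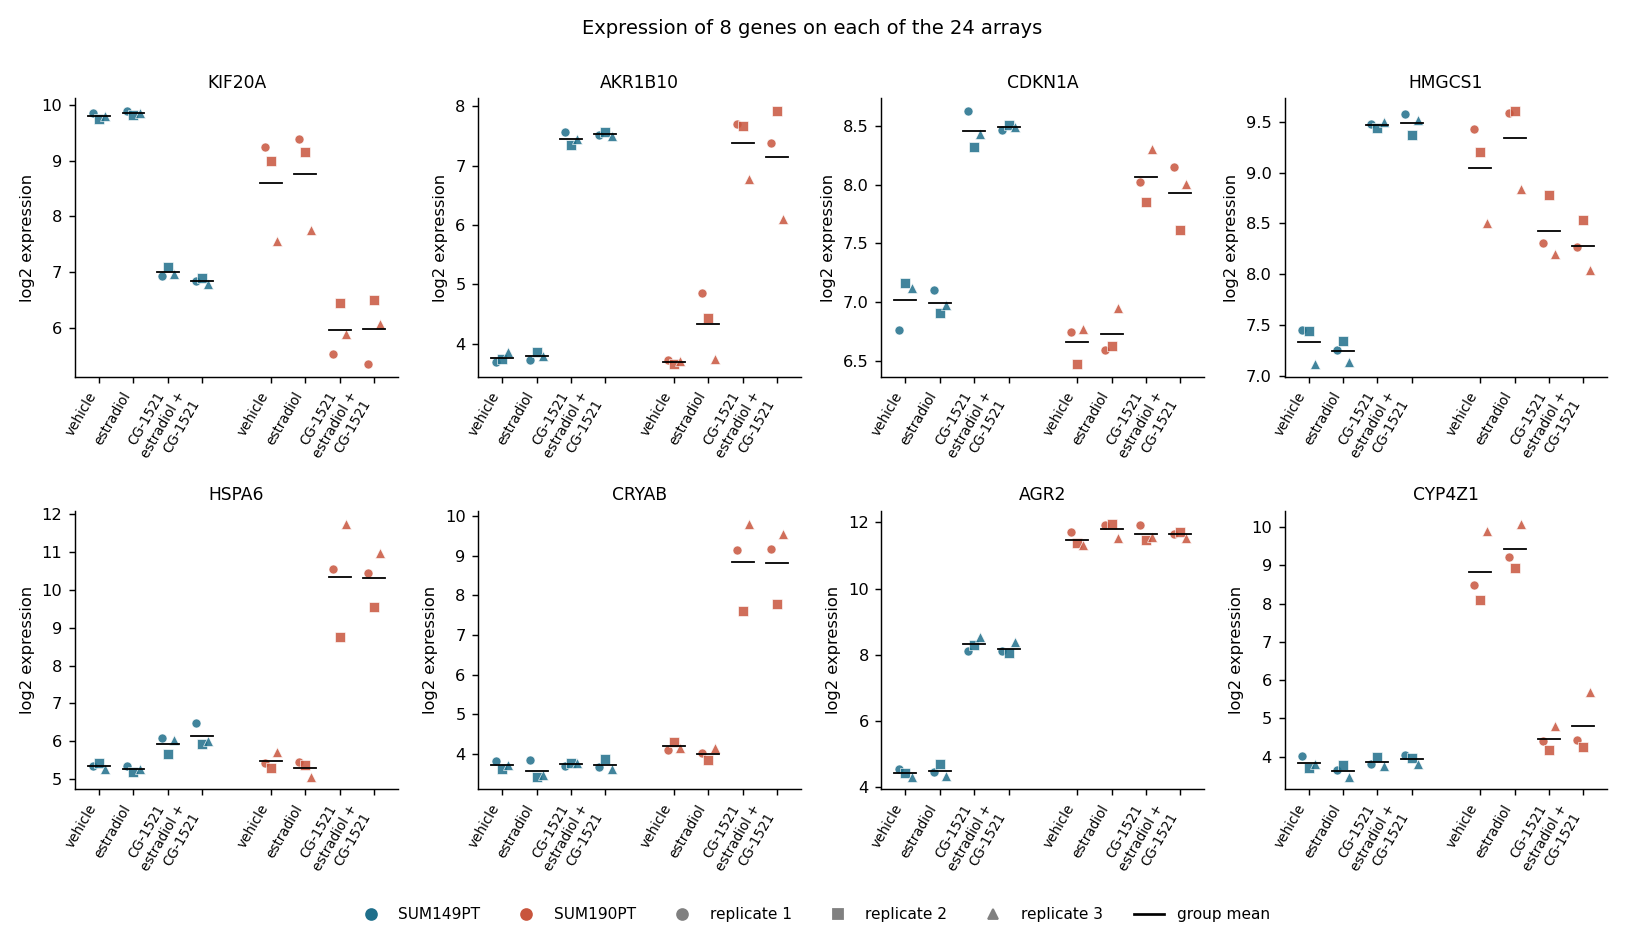
The log2 expression of 8 named genes is plotted for each of the 24 arrays, by treatment, with colour for the line, marker shape for the replicate and a bar for the mean of 3 arrays. With CG-1521 AKR1B10 rose by 3.69 in SUM149PT and 3.68 in SUM190PT, whereas HSPA6 rose by 4.88 and CYP4Z1 fell by 4.37 in SUM190PT.

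Whether the response to CG-1521 differed between the lines was tested as the SUM149PT change minus the SUM190PT change, which dose and medium could also affect. Cholesterol synthesis moved apart in 17 of 18 genes (median 1.69), with MSMO1 at 3.14 (SE 0.276), HMGCS1 at 2.75 (SE 0.293), the sterol sensor INSIG1 at 2.44 (SE 0.239) and SQLE at 2.37 (SE 0.277), all towards SUM149PT. Fatty acid synthesis did so in 10 of 12 (median 1.27), with FADS2 at 3.30 (SE 0.415) and THRSP at 3.04 (SE 0.235). Heat shock genes moved the other way in 12 of 13 (median −1.44), with HSPB8 at −4.42 (SE 0.415), HSPA6 at −4.30 (SE 0.615) and HSPH1 at −3.18 (SE 0.366), as did CRYAB (−4.62, SE 0.533) and CASP14 (−4.26, SE 0.954). For HSPB8 and CRYAB nearly all of the difference was the rise in SUM190PT (4.54 and 4.66). Luminal markers differed towards SUM149PT in 7 of 16 and away in 1 (median 0.61), with AGR2 at 3.70 (SE 0.211), TFAP2B at 2.35 (SE 0.270) and SPDEF at 1.88 (SE 0.264). The TFAP2B and SPDEF differences were close in size to their falls in SUM190PT given above, whereas AGR2 rose in SUM149PT. CYP4Z1 (4.38, SE 0.510), FGG (3.57, SE 0.466) and MAGED1 (3.56, SE 0.167) led the single genes. For CYP4Z1 and FGG nearly all of the difference was the fall in SUM190PT (−4.37 and −3.47). The camera adjusted p was 1.6e-21 for cholesterol synthesis, which held with an estimated correlation (adjusted p = 0.0431). The call was lost at adjusted p = 0.0723 with an estimated correlation when the third SUM190PT vehicle and estradiol arrays were left out. The camera value was 8.68e-10 for fatty acid, 3.62e-14 for heat shock and 1.7e-06 for luminal genes, each at adjusted p = 0.0729 with an estimated correlation. Unfolded protein response genes differed in 7 of 19 upwards and 1 downwards (median 0.74, adjusted p = 0.0024, or adjusted p = 0.566 with an estimated correlation), with the kinase EIF2AK3 at 1.21 (SE 0.156) and ATF3 at −1.85 (SE 0.567). The third SUM190PT vehicle array lay high in this list, and without it and the third estradiol array the median was 0.386 (adjusted p = 0.0125, or adjusted p = 0.583 with an estimated correlation).

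Smaller list differences lay towards SUM190PT. Histone genes differed in 4 of 12 (median −0.58), acetyltransferase genes in 4 of 12 (−0.38) and antigen presentation genes in 5 of 10 with 1 the other way (−0.51). Mesenchymal genes differed in 5 of 14 with 1 the other way (−0.45), glycolysis genes in 5 of 20 (−0.33) and fibroblast markers in 4 of 12 (−0.22). Examples were the linker histone H1-2 (−1.40, SE 0.281), PSMB8 (−1.05, SE 0.172), TGFBI (−2.74, SE 0.366), CDH2 (−2.14, SE 0.226), the vasodilator peptide gene ADM (−1.36, SE 0.165) and FAP (−2.36, SE 0.144). The calls at adjusted p = 0.00666, 0.00308, 0.0238, 0.00754, 0.0024 and 0.0124 were lost at adjusted p = 0.461, 0.144, 0.155, 0.0826, 0.483 and 0.143 with an estimated correlation. Fibroblast markers had medians of 4.546 to 4.833 on the SUM190PT vehicle arrays, near those arrays' lower quartiles (4.491 to 4.615). A fall there could hardly be read. Mesenchymal genes were mostly lower in SUM190PT already in vehicle. The TGFBI, CDH2 and FAP differences were close in size to their falls in SUM149PT given above. A difference was not detected for spindle genes (0 of 29, median −0.25, adjusted p = 0.442), G2/M genes (0 of 18, −0.05, 0.853), or DNA replication genes (1 of 29, −0.36, 0.099). Nor was it for NF-kB genes (4 up and 3 down of 19, 0.703), interferon genes (1 up and 7 down of 23, 0.0697), oxidative phosphorylation genes (4 up of 22, 0.0633) or basal markers (1 up and 3 down of 10, 0.451). Other settings called some of these. Quantile normalization called interferon (adjusted p = 0.0338) and oxidative phosphorylation genes (0.00162), and without SUM190PT vehicle replicate 1 spindle (0.0218) and DNA replication genes (0.00541) were called towards SUM190PT. With an estimated correlation these 4 were lost at adjusted p = 0.756, 0.422, 0.914 and 0.888. Without the third SUM190PT vehicle and estradiol arrays these medians turned the other way and were not called, at 0.20 for spindle (adjusted p = 0.228), 0.22 for G2/M (0.211) and 0.17 for DNA replication genes (0.581). CDKN1A was at 0.04 (SE 0.205, adjusted p = 0.906), while EGFR differed by −1.13 (SE 0.176). The counts adjusted over the list alone gave that 17 cholesterol and 11 fatty acid genes differed upwards, 13 heat shock genes downwards and 8 luminal markers upwards. In limma, 3801 genes differed, 1660 upwards and 2141 downwards (43.7% upwards, or 30% with each array centred), of which 435 and 483 by at least 2-fold.

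Genes shared by the 2 responses were counted over the 18417 genes. Raised in both lines were 648 genes, against 221 if the calls were independent (a ratio of 2.93, Fisher's exact test, two-sided p = 6.9e-174), and lowered in both were 636 against 303 (a ratio of 2.10, p = 1.14e-93). AKR1B10, MAP1B, HDAC9, CDKN1A and CXCL8 were among the former and KIF20A, ASPM and BIRC5 among the latter. Raised in SUM149PT but lowered in SUM190PT were 143 genes against 219, and the reverse held for 185 against 305. Across genes, the log2 changes of the lines correlated at r = 0.37 (Spearman 0.239), and genes are not independent replicates.

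**Figure D3:**
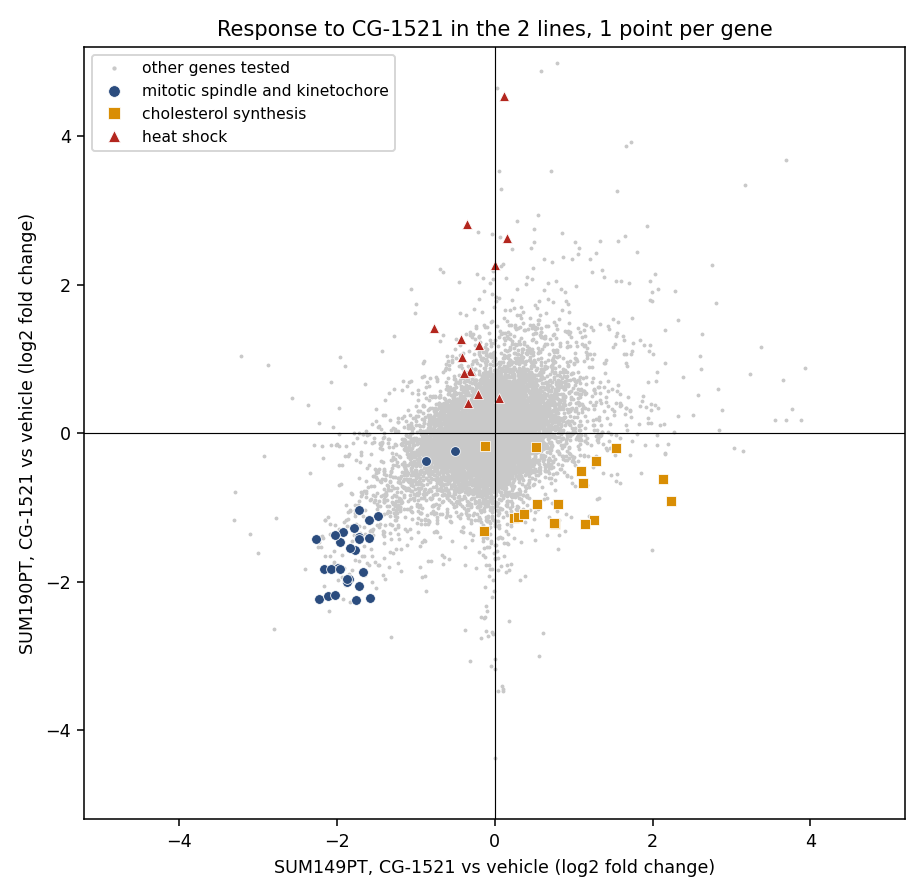
The log2 fold change with CG-1521 against vehicle in SUM149PT is plotted against that in SUM190PT, 1 point per gene, with spindle, cholesterol synthesis and heat shock genes coloured. Spindle genes lay low in both lines, 16 of 18 cholesterol genes rose in SUM149PT where 13 fell in SUM190PT, and all 13 heat shock genes rose in SUM190PT.

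Estradiol was compared with vehicle to ask whether lines labelled receptor negative respond to the hormone. In SUM149PT no gene passed in limma, at a smallest adjusted p of 0.863, and 845 genes lay at an unadjusted p under 0.05 where chance gives 921. Of 25 estrogen response genes 0 passed (median −0.03, camera adjusted p = 0.653). GREB1 was at −0.14 (SE 0.082) and the trefoil gene TFF1 at 0.13 (SE 0.113, n = 3), and ESR1 was at 0.10 (SE 0.096). Camera and fry called no list (camera's smallest adjusted p = 0.239). The other settings also gave 0 genes, except that leaving out vehicle replicate 1 gave 1.

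In SUM190PT estradiol raised 1 gene at the threshold, KRCC1, a coiled-coil protein gene, from 6.32 ± 0.104 to 7.19 ± 0.030 (SD, n = 3; log2 change 0.86, SE 0.098, limma adjusted p = 0.0155). Classical targets did not pass as a group. In their list 0 of 25 estrogen response genes passed (median −0.03, camera adjusted p = 0.858), with TFF1 at −0.17 (SE 0.180) and GREB1 at −0.13 (SE 0.095). GPER1 was at −0.57 (SE 0.104), the pro-apoptotic BBC3 at −0.98 (SE 0.214) and the luminal marker AGR3 at 1.36 (SE 0.307), with adjusted p of 0.0541, 0.0541 and 0.0552. Camera called no list (smallest adjusted p = 0.0752), while fry called neuronal genes down (median −0.205, adjusted p = 0.0342). Without the third vehicle and estradiol arrays spindle genes were called up (median 0.32, adjusted p = 0.00159) and neuronal genes down (camera 0.0264), each at adjusted p = 0.869 with an estimated correlation. At an unadjusted p under 0.05 there were 4531 genes where chance gives 921, and the groups did not overlap for 28.4% of genes, against 10% by chance. The replicate numbers paired these arrays by the rule used, but arrays of unlike number correlated at up to 0.447, so the pairing is uncertain. With the replicate block 519 genes passed in limma, 256 up and 263 down, among them GPER1, BBC3 and AGR3, each at adjusted p = 0.0442. With the block camera called no list (smallest adjusted p = 0.0566). Leaving out vehicle replicate 1 gave 2261 genes, and leaving out any other of the 6 arrays gave 0. That array correlated across genes at 0.9949 and 0.9923 with estradiol replicates 1 and 2, above 0.991 and 0.9807 with vehicle replicates 2 and 3. Why it lay closer to estradiol arrays was not tested.

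Adding estradiol to CG-1521 was compared with CG-1521 alone to ask whether the hormone alters the response. No gene passed in either line. Limma's smallest adjusted p was 0.14 in SUM149PT, with 1156 genes at an unadjusted p under 0.05, and 0.735 in SUM190PT, with 889. In SUM149PT 5 lists lay slightly lower as groups with 0 genes past the threshold. They were metallothioneins (median −0.20, camera adjusted p = 0.000114), spindle (−0.05, 0.0213), oxidative phosphorylation (−0.06, 0.0249), tubulin (−0.06, 0.0254) and ribosomal protein genes (−0.07, 0.0254), all at adjusted p = 0.512 with an estimated correlation. Metallothioneins, adjusted over the list alone, passed in 4 of 8. In SUM190PT camera and fry called no list (camera's smallest adjusted p = 0.185), CDKN1A was at −0.14 (SE 0.166) and GPER1 at 0.25 (SE 0.104). Its count was 0 under the other settings too, the replicate block included, except 7 with all 24 arrays in one fit.

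The combination against vehicle and against estradiol gave the effect of CG-1521 beside the hormone. In SUM149PT the combination against estradiol raised SPX (4.05, SE 0.135), CLGN (3.78, SE 0.129), AKR1B10 (3.74, SE 0.081) and AGR2 (3.69, SE 0.127), and lowered EFEMP1 (−3.42, SE 0.128), RARRES1 (−3.26, SE 0.166), H2BC14 (−3.08, SE 0.090) and H1-5 (−3.02, SE 0.099). All 29 spindle genes fell (median −1.92), 15 of 18 cholesterol genes rose (median 0.82) and all 19 unfolded protein response genes rose (median 0.82), at camera adjusted p = 4.82e-31, 1.79e-10 and 9.03e-13, which held with an estimated correlation (adjusted p = 0.0283, 0.0488 and 0.032). In SUM190PT it raised HSPA6 (5.03, SE 0.555), BPIFC (4.98, SE 0.379), CRYAB (4.82, SE 0.484) and HSPB8 (4.39, SE 0.365), and lowered CYP4Z1 (−4.62, SE 0.464), FGG (−4.18, SE 0.419), SCGB1D2 (−4.12, SE 0.536) and LRRC31 (−4.12, SE 0.323). There 27 of 29 spindle genes fell (median −1.99), 16 of 18 cholesterol genes fell (median −1.04) and 11 of 13 heat shock genes rose (median 1.04), at adjusted p = 5.04e-15, 8.99e-12 and 5.48e-08. No list held there, the lowest being adjusted p = 0.303 with an estimated correlation, while fry called 18 of 34 lists. Limma called 6791 genes in SUM149PT (3031 up, 3760 down) and 4732 in SUM190PT (2306 up, 2426 down). The SUM190PT count was 2605 without estradiol replicate 2, 2679 without combination replicate 1 and 3063 without combination replicate 3. This contrast shares no array with CG-1521 against vehicle, and across genes the log2 changes of the 2 contrasts correlated at r = 0.938 (Spearman 0.818) in SUM149PT and 0.709 (0.402) in SUM190PT.

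Against vehicle, the combination in SUM149PT raised SPX (3.86, SE 0.135), AKR1B10 (3.76, SE 0.081), AGR2 (3.75, SE 0.127) and CLGN (3.70, SE 0.129), and lowered EFEMP1 (−3.39, SE 0.128), RARRES1 (−3.26, SE 0.166), CASP14 (−3.11, SE 0.181) and H2BC14 (−3.06, SE 0.090). All 29 spindle genes fell (median −1.92, camera adjusted p = 2.77e-30, or 0.0261 with an estimated correlation) and 14 of 18 cholesterol genes rose with 1 fallen (median 0.76, adjusted p = 7.07e-10, or adjusted p = 0.0567 with an estimated correlation). In SUM190PT it raised BPIFC (4.92, SE 0.379), HSPA6 (4.85, SE 0.555), CRYAB (4.63, SE 0.484) and HSPB8 (4.34, SE 0.365), and lowered CYP4Z1 (−4.04, SE 0.464), SCGB1D2 (−3.83, SE 0.536), LRRC31 (−3.60, SE 0.323) and FGG (−3.50, SE 0.419). Of its lists 14 were called by camera, with heat shock up in 12 of 13 (median 1.23, adjusted p = 2.23e-13) and cholesterol synthesis down in 14 of 18 (median −0.96, adjusted p = 4.38e-12). None held (lowest adjusted p = 0.237 with an estimated correlation), while fry called 12 of 34 lists. Limma called 6848 genes in SUM149PT (2990 up, 3858 down) and 2466 in SUM190PT (1220 up, 1246 down), the latter 1611 without vehicle replicate 2 and 1252 without combination replicate 1.

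The interaction of estradiol with CG-1521, the change with both against that with each alone, was tested within each line. In SUM149PT 0 genes passed in limma (smallest adjusted p = 0.762, 1046 at an unadjusted p under 0.05), and no other setting called any except 1 gene without vehicle replicate 1 and 1 without estradiol replicate 3. Its lists lay slightly down for metallothioneins (median −0.15, camera adjusted p = 0.00853), ribosomal protein genes (−0.09, 0.0106), spindle genes (−0.06, 0.0341) and oxidative phosphorylation genes (−0.05, 0.0341), each at adjusted p = 0.656 with an estimated correlation. In SUM190PT 95 genes passed, 69 up and 26 down, led by the keratin-associated KRTAP10-1 (1.54, SE 0.297) and KRTAP10-4 (1.29, SE 0.209), the sulfotransferase CHST14 (1.45, SE 0.271) and CFAP77 (1.23, SE 0.226). The largest falls were in TAS2R19, a taste receptor (−1.54, SE 0.214), METTL15 (−1.34, SE 0.221), RPL22 (−1.25, SE 0.215) and ZNF429 (−1.24, SE 0.230), with adjusted p from 0.0416 to 0.0483. GPER1 passed as well (0.82, SE 0.148, adjusted p = 0.0476), and neuronal genes lay up as a list (median 0.24, camera adjusted p = 0.0283, or adjusted p = 0.992 with an estimated correlation). The count rested on single choices. It was 0 with the replicate block, 5 (0% up) with quantile normalization and 10 (10% up) with centring, against 72.6% up. It was 1655 without vehicle replicate 1, 4 without combination replicate 2, 1 without estradiol replicate 3 and 0 without any other of the 12 arrays.

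Whether the lines differed in their response to estradiol was tested in the same way, and 321 genes passed in limma, 169 upwards and 152 downwards (SUM149PT change minus SUM190PT change). The largest were the interferon lambda gene IFNL2 (1.28, SE 0.284), POU5F1P3 (1.21, SE 0.301), BBC3 (1.12, SE 0.262) and SORBS3 (1.08, SE 0.214) upwards, and AGR3 (−1.43, SE 0.345), the glucuronosyltransferase UGT2B7 (−1.33, SE 0.327), POF1B (−1.22, SE 0.289) and ZNF845 (−1.15, SE 0.276) downwards. In SUM149PT vehicle AGR3, UGT2B7 and POF1B had mean levels of 2.97, 3.18 and 3.74, below the arrays' lower quartiles (4.54 to 4.57). A response there can hardly be read, so their differences rest on SUM190PT. GPER1 differed by 0.74 (SE 0.152, adjusted p = 0.0358). Camera called no list (smallest adjusted p = 0.139), while fry called neuronal genes upwards (median 0.17, adjusted p = 0.0309). With the replicate block the count was 575, and with centring 27.5% lay upwards, against 52.6%, while quantile normalization left 2 genes, both upwards. Single arrays moved the count. It was 7, 1 and 103 without SUM149PT vehicle replicates 1, 2 and 3, and 0, 4 and 0 without SUM149PT estradiol replicates 1, 2 and 3. It was 2239, 0 and 3 without SUM190PT vehicle replicates 1, 2 and 3, and 181 and 0 without SUM190PT estradiol replicates 1 and 2.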

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

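The tests of a CG-1521-treated culture, of a state shared by the third experiment, of estrogen target genes, of convergence between the lines and of splits that part all 6 pairs were chosen only after the result was seen.

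Cholesterol synthesis genes rose with CG-1521 in SUM149PT and fell in SUM190PT. The camera call of the SUM190PT fall was lost at adjusted p = 0.399 with an estimated correlation, or 0.292 with it and without the 2 arrays that stand apart. The test of the difference between lines called the list (median 1.69, adjusted p = 0.0431 with an estimated correlation, or 0.0723 with it and without the 2 arrays) and, beside it, fatty acid synthesis (1.27, lost at adjusted p = 0.0729 with an estimated correlation). Neither scaling of the arrays accounts for it: under quantile normalization and median centring the SUM149PT median was 0.89 and 0.78 and the SUM190PT median −0.98 and −0.863. Nor does the third vehicle array, since the SUM190PT median was −0.958 without it and the third estradiol array. A drift of both lines to 1 level also fails, because the lines did not meet but crossed: SUM149PT minus SUM190PT was −0.845 in vehicle and 0.9 under CG-1521, where 15 of 18 genes were higher in SUM149PT against 3 of 18 before. What stays open is whether line, CG-1521 dose or serum in the medium, which supplies cholesterol, sets the direction, and a line difference in how sterol genes answer CG-1521 may be followed up as a hypothesis at matched dose and medium.

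The third vehicle and the third estradiol arrays of SUM190PT lay low in DNA replication genes (−1.63 and −1.72) and high in unfolded protein response genes (0.69 and 0.74), and their deviations correlated at 0.729 across genes. A CG-1521-treated culture behind these labels is argued against, since the genes that CG-1521 raised at least 2-fold moved by at most 0.07 of its effect (median ratio). A narrower signal range does not account for it either, since the trend of the deviations on expression level reached at most 0.091 and with it removed the replication median stayed at −1.594 or lower, but RNA quality was not tested. A state shared by the third experiment was sought over 10821 genes that CG-1521 barely moved. The deviations of the third CG-1521 and combination arrays correlated there with those of the 2 arrays at no more than 0.093. The 2 arrays correlated at 0.508 with each other, so these genes argue against a shared state. Division genes that CG-1521 lowered lie outside that set, so a shared slow-growing state limited to them could not be tested this way. A slower-growing state of the cultures without CG-1521 in that experiment, denser or depleted of nutrients, may remain as a hypothesis. That hypothesis was not tested, since the labels give no explanation.

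SUM190PT estradiol and vehicle arrays differed in 4531 genes at an unadjusted p under 0.05 but in 1 after adjustment, or 519 with the replicate block. Arrays of equal number correlated at 0.443, 0.229 and 0.729, but those of unlike number reached 0.447, so the pairing behind the block is uncertain. In log2 values vehicle replicate 1 lay closest to estradiol replicate 1 (r = 0.9949), above its own group (0.991 and 0.9807), and why was not tested. A difference in signal range is argued against as the whole cause: the interquartile range was 3.35 ± 0.065 with estradiol and 3.09 ± 0.127 with vehicle, and quantile normalization brought the correlation of fold change with expression from 0.331 to −0.004, yet left 3370 genes. Spread from the third arrays stays open: without them 0 genes passed, but that leaves 2 arrays against 2, and the median SE rose from 0.139 to 0.159 although the residual SD fell from 0.171 to 0.16, so this count cannot decide, and nor can array weights (3079 genes), which were low for these arrays (0.57 and 0.511) but also for vehicle replicate 1 (0.623), without which alone 2261 passed. A rise of classical targets as a group is argued against, since with the block the estrogen response list had a median of −0.029, 12 members up, 13 down and 0 past the threshold. Changes of single targets in either direction stay open. With the second smallest adjusted p at 0.0541 and 495 genes under 0.06, the count without the block may sit at the edge of the threshold, and whether the pairing is modelled changes the call.

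Other results in which the lines differed in their answer to CG-1521 were the count of 3801 genes. The list medians of that difference were −1.44 for heat shock, 0.61 for luminal markers, 0.74 for the unfolded protein response, −0.58 for histones, −0.38 for acetyltransferases, −0.51 for antigen presentation, −0.45 for mesenchymal genes, −0.33 for glycolysis and −0.22 for fibroblast markers. The unfolded protein response median was 0.386 without the 2 arrays that stand apart. All 9 calls were lost with an estimated correlation, at adjusted p = 0.0729, 0.0729, 0.566, 0.461, 0.144, 0.155, 0.0826, 0.483 and 0.143 in that order. Without the dimmest 50% of genes the mesenchymal (0.283), fibroblast (0.84), histone (0.0958) and glycolysis (0.0539) calls ended as well. Without the dimmest 25% the antigen presentation (0.0628) and fibroblast (0.0741) calls ended, and under quantile normalization that for glycolysis (0.0571). Fibroblast markers lay near the arrays' lower quartile in SUM190PT, so a fall there could hardly be read. Single genes were CYP4Z1 (4.38), AGR2 (3.70), FGG (3.57), MAGED1 (3.56), CRYAB (−4.62), HSPB8 (−4.42), HSPA6 (−4.30) and CASP14 (−4.26). For CYP4Z1, FGG, CRYAB and HSPB8 nearly all of the difference was the change in SUM190PT. The answer to estradiol differed between the lines in 321 genes, with IFNL2 (1.28), POU5F1P3 (1.21), BBC3 (1.12), SORBS3 (1.08), AGR3 (−1.43), UGT2B7 (−1.33), POF1B (−1.22) and ZNF845 (−1.15). AGR3, UGT2B7 and POF1B lay below the arrays' lower quartile in SUM149PT, so their differences rest on SUM190PT. The interaction of estradiol and CG-1521 in SUM190PT passed in 95 genes, with KRTAP10-1 (1.54), CHST14 (1.45), KRTAP10-4 (1.29), CFAP77 (1.23), TAS2R19 (−1.54), METTL15 (−1.34), RPL22 (−1.25) and ZNF429 (−1.24), and in neuronal genes as a list (0.24, lost at adjusted p = 0.992 with an estimated correlation). This count was 0 with the replicate block, 5 with quantile normalization and 10 with centring. In SUM149PT the interaction passed in 0 genes in limma, with 1046 at an unadjusted p under 0.05, and called spindle (−0.063), metallothionein (−0.146), ribosomal protein (−0.088) and oxidative phosphorylation genes (−0.051) as lists, all lost at adjusted p = 0.656 with an estimated correlation. Among the 12083 probe sets without an annotation entry, which the gene tests left out, 1039 passed with CG-1521 in SUM149PT (539 up, 500 down) and 646 in SUM190PT (528 up, 118 down, and 242 up against 17 down at 2-fold).

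Other splits of the same arrays were counted for every contrast. For the 2-group contrasts there are 10 splits, too few for a share under 0.05: the real counts were 6319, 6848 and 6791 in SUM149PT, 3053, 2466 and 4732 in SUM190PT and 8592 between the lines, with a highest other count of 0 in each, 1 split of 10 reaching the real count. Every other split there mixes the compared groups on both sides. A real difference then enters the spread and holds the count down, so these counts of 0 cannot decide on chance. For SUM149PT estradiol against vehicle and for SUM190PT combination against CG-1521 the real and the highest other count were 0, and for SUM149PT combination against CG-1521 they were 0 and 1, so all 10 splits matched. For SUM190PT estradiol against vehicle the real count was 1 and 3 of 10 splits reached it. The highest other, 427, set vehicle replicate 1 with estradiol replicates 1 and 2 against vehicle replicates 2 and 3 with estradiol replicate 3. That split still sets most estradiol arrays against most vehicle arrays. It therefore cannot tell treatment from another structure of the samples. Among the 4 splits that part all 3 pairs the highest other was 0. With 100 splits, 1 of 100 reached the real count for the CG-1521 response between lines (3801, highest other 3169). These splits mix treated and vehicle arrays within a line, so the effect of CG-1521 itself enters their spread. That share therefore cannot decide whether the responses of the lines differ. For the SUM190PT interaction without the block, 1 of 100 splits reached the real count, by a narrow margin (95, highest other 91). Among the 32 splits that part all 6 pairs of that interaction the highest other was 0 without the block. The block gives each replicate number 1 effect across all 4 groups, although CG-1521 and vehicle arrays of equal number were not paired (−0.01, 0.101 and 0.055). With that block the real count was itself 0 and all 32 matched it, so the 2 fits leave the interaction open. Without the block it was 0 as well when any of 9 of the 12 arrays was left out. Chance was not excluded for the SUM149PT interaction (0, highest other 1, 100 of 100) or for the estradiol response between lines (321, highest other 768, 5 of 100).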

How the results depend on the processing

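The settings without the third SUM190PT vehicle and estradiol arrays, and the compared groups alone with the block, were chosen after seeing the data. Counts with CG-1521 in SUM149PT and the difference between lines in the CG-1521 response stayed within 1.5 times under every setting run (6319, range 4827 to 8093, and 3801, range 3029 to 4713). No named gene that was called changed sign, nor did a called list in the CG-1521 contrast of either line or between lines, the 3 contrasts whose lists were run through every setting, but the balance of counts did turn. The SUM190PT interaction went from 72.6% up to 0% of 5 genes with quantile normalization and 10% of 10 with centring, and the estradiol response between lines from 52.6% to 27.5% upwards with centring. Named genes past the threshold in every setting were 118 of 136 for CG-1521 in SUM149PT, 79 of 104 in SUM190PT, 127 of 136 for vehicle between lines and 83 of 104 for the CG-1521 response between lines; lists were 5 of 15, 0 of 15 and 0 of 11 for the CG-1521 contrasts, the estimated correlation being the setting that ended most calls. Precision was lower in SUM190PT, where arrays of a group differed more.

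With the replicate block SUM190PT estradiol against vehicle gave 519 genes in place of 1 and the SUM190PT interaction 0 in place of 95. The estradiol response between lines gave 575 in place of 321, and the block moved no other count past 1.5 times. With the block and only the compared groups, SUM190PT estradiol gave 2013. Only the compared groups gave 0 for SUM190PT estradiol and for the estradiol response between lines, where fewer arrays estimate the variance. With all 24 arrays in one fit, SUM190PT counts were 5070 for CG-1521, 2990 for estradiol, 4242 for the combination against vehicle, 7 for the combination against CG-1521 and 2540 for the interaction, a fit in which the tighter SUM149PT arrays lower the SUM190PT variance. Quantile normalization gave 4 for SUM190PT estradiol, 5 for its interaction and 2 for the estradiol response between lines, and centring gave 10 for the interaction. Without the dimmest 50% of genes estradiol gave 2 and the interaction 1. All probe sets gave 649 and 359 for these, and 13005 for vehicle between lines. Array weights gave 3079 for estradiol, 7203 for the combination against estradiol, 1814 for the interaction and 2621 for the estradiol response between lines, and trend and robust variances gave 4 for the interaction. Without the 2 arrays estradiol gave 0, the interaction 1 and the estradiol response between lines 2. Where no reason is given the cause was not tested.

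Leaving out each array in turn gave 1567 to 3082 genes for CG-1521 in SUM190PT, 0 to 2261 for estradiol, 1252 to 2248 for the combination against vehicle, 2605 to 4513 against estradiol, 0 to 1655 for the interaction and 0 to 2239 for the estradiol response between lines. The highest of the estradiol, interaction and estradiol response counts came without SUM190PT vehicle replicate 1. In SUM149PT the range was 0 to 1 for estradiol and for the interaction. With a 2-fold change asked as well, 80 genes were raised and 114 lowered in both lines, in place of 648 and 636, since the rule is stricter.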

Other observations

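The test on small nucleolar RNAs was chosen only after the result was seen. The tests on NRF2 targets and histone genes used members whose values with CG-1521 had not been looked at. Of these, the histone gene H3C11 had been named for its difference between the lines in vehicle.

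Genes that defend against oxidative stress rose with CG-1521 in SUM149PT and, in part, in SUM190PT. The aldo-keto reductases and the cystine transporter that led the rises in SUM149PT are known targets of the transcription factor NRF2, so 20 other measured NRF2 targets were tested. In SUM149PT 17 rose and 0 fell (median 0.69), including sulfiredoxin SRXN1 (1.33, SE 0.079), the ferritin light chain FTL (1.73, SE 0.081) and the glutathione synthesis subunit GCLM (0.67, SE 0.097). In SUM190PT 11 rose and 0 fell (median 0.58), with SRXN1 at 2.59 (SE 0.388), FTL at 1.56 (SE 0.156) and GCLM at 1.81 (SE 0.352); the quinone reductase NQO1 did not pass in either line (0.05 and 0.17). The camera p was 5.13e-12 in SUM149PT and 2.99e-07 in SUM190PT, or 6.72e-05 and 0.11 with an estimated correlation, so a shared NRF2 response may be put forward as a hypothesis for both lines, firmer in SUM149PT.

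Replication-dependent histone genes fell in SUM149PT, where H1-5, H2BC14 and H1-1 were among the largest falls. Of 37 other measured histone genes 31 fell and 0 rose (median −1.24), with H1-4 at −2.17 (SE 0.081), at a camera p of 2.59e-18, or 0.00678 with an estimated correlation. In SUM190PT 6 of 37 fell (median −0.43, camera p = 0.000834, or 0.416 with an estimated correlation). These transcripts are made in S phase, and the fall in SUM149PT is consistent with the fall of DNA replication genes there.

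Small nucleolar and Cajal body RNAs, 192 measured, guide the modification of ribosomal and spliceosomal RNA. With CG-1521 58 rose and 1 fell in SUM190PT (median 0.35, camera adjusted p = 2.1e-17, estimated-correlation p = 0.000991). In SUM149PT 44 rose and 11 fell (median 0.07, adjusted p = 0.0032, estimated-correlation p = 0.347). The combination against estradiol, which shares no array with these contrasts, gave 42 up and 11 down in SUM190PT (median 0.064, camera adjusted p = 0.234, estimated-correlation p = 0.471). In SUM149PT it gave 36 up and 28 down (median 0.018, camera adjusted p = 0.585, estimated-correlation p = 0.836). As a group they were thus called with CG-1521 against vehicle but not against estradiol. With estradiol in SUM190PT 132 were positive with 0 past the threshold (median 0.18, adjusted p = 7.17e-09, estimated-correlation p = 0.00904), and with the replicate block 19 rose and 1 fell where 2.67 were expected to rise. With estradiol in SUM149PT 139 were positive and 0 passed (median 0.10, adjusted p = 2.28e-14, estimated-correlation p = 0.0346). Beside CG-1521 estradiol did not raise them. In SUM190PT 64 were positive when estradiol was added to CG-1521 (median −0.062, adjusted p = 1.35e-06, estimated-correlation p = 0.0212), and the interaction had a median of −0.20 (estimated-correlation p = 0.00639). In SUM149PT 99 were positive when it was added (median 0.005, adjusted p = 0.881), so no common direction with estradiol was shown.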
